A study of Homo sapiens with 6 samples.

How the data were processed

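Total RNA of the prostate epithelial line RWPE-1 and of its arsenite-transformed descendant CAsE-PE was measured on single-colour whole-transcript arrays. Per the labels, cells were grown in keratinocyte serum-free medium with bovine pituitary extract and epidermal growth factor, RNA was extracted with Trizol and a Qiagen column kit, and biotin-labelled target was made with an Ambion kit. The authors deposited 1 intensity per feature and array, on a linear scale, for 33252 features and 6 arrays. The values are positive and were judged linear from their range, since they reach 16617. The background correction, summarisation and normalisation behind these intensities are not given in the sources used here. The deposited columns had similar but not identical quantiles, with medians of 93.3, 94.7 and 97.2 in RWPE-1 at passages 18, 38 and 42 and of 92.3, 92.0 and 91.7 in CAsE-PE at 30, 33.5 and 35 weeks. No detection call or background value accompanied the intensities used here, so low values cannot be told from background.

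Genes were named through the platform annotation supplied with GEO. It gave 1 gene symbol for 19460 features, several for 1754 and did not list 12038, which were left unnamed. Of the features with 1 symbol, 19425 had an Entrez identifier in the RefSeq table of assembly GRCh38.p14, and 0 symbols needed an update. That table also gave the chromosome and the order of 18385 genes, the order from its start coordinates, which were used for nothing else. Each of 18417 genes was represented by the feature with the highest mean over all arrays. Among 769 genes with several features, 1 had called features in opposite directions, CRACR2A. The genes H4C14 and H4C15 had identical values on all arrays.

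The design foresaw log2 values, with log2(value + 1) if the table proved linear. It did, and a pseudocount of 1 was used, so fold changes of dim genes are understated. Groups came from the phenotype label, with passage or exposure time naming the arrays. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 4 residual degrees of freedom), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p-values of genes come from this fit unless another model is named. Passage within RWPE-1 and weeks within CAsE-PE were tested in a second limma model with the group, which has 2 residual degrees of freedom. Before the data were examined, the design, the first set of alternatives, the gene lists and the rule for named genes were fixed.

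Named genes were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 2 rises and 2 falls among called members of each list, 12 genes fixed in advance of which 7 were measured, and up to 3 rises and 3 falls per trend. Genes on chromosome Y and XIST were left out of this rule. Further list members were chosen after their values were seen, as examples. The 29 lists covered C2H2 zinc finger genes, HOX genes, clustered protocadherins, cancer/testis antigens, metallothioneins, NRF2 targets, arsenic handling, stress proteins, basal, luminal and squamous markers, junction and mesenchymal genes, proliferation, p53 targets, interferon response, MHC genes, inflammatory cytokines, the RAS and MAPK pathway, methylation machinery, cholesterol synthesis, hypoxia and glycolysis, stem cell genes, fibroblast, leukocyte, endothelial and neuroendocrine markers, ribosomal proteins and histones. Several genes stand in more than 1 list, such as SLC2A1, ENO2 and ITGA2. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the lists.

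Chromosomes were compared with Fisher's exact test in scipy 1.17.1, adjusted over chromosomes and directions. All Fisher tests count genes as independent, though neighbours and family members can move together. Adjacent genes were tested against 1000 shuffles of gene order within chromosomes. After the data were seen, genes outside the dimmest 33.3% (12253 with a position) were put into 493 windows of 25 neighbours. Chromosome Y was left out of both the adjacent-gene test and the windows. A window was past the limit when its median differed from that of all genes by more than 0.345, the level that the largest of all windows passed in 5% of 1000 shuffles. A second set of differences was made with each gene's window median taken off. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.

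Alternatives were quantile normalisation, centring on array medians, a filter on dim genes, other rules per gene, other variance models, array weights, a test against a 1.5-fold change, covariates and each array left out in turn. Where a call was lost with an array left out, the array that gave the highest adjusted p is named, and the call was often lost with others as well. The steps were tested on simulated data. For the fits, real gene means were used with the real spreads shuffled among genes and with independent noise. In the group comparison 50 genes were changed at each size, far fewer than were called, so recovery in the real data may differ. For windows, the real differences were shuffled and blocks were moved. For the group comparison over 18417 genes, 28% of genes changed by 0.5 on the log2 scale were recovered, 76% at 1, 96% at 2 and 100% at 3, with 0.049% false calls. For the passage trend, 78.5% of changes of 2 over the range were recovered. For windows over 12253 genes, 25% of shifts of 0.3 and 100% of shifts of 0.5 were recovered. Features with several or no symbols entered no comparison between genes.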

Results

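Gene expression was measured on 6 single-colour arrays of human prostate epithelial cells. RWPE-1 is a non-tumorigenic line derived from normal adult prostate epithelium and immortalised with human papillomavirus 18. CAsE-PE is its malignantly transformed descendant, obtained by continuous growth in 5 µM sodium arsenite. The RWPE-1 group held 3 untreated arrays, from passages 18, 38 and 42, named replicates 1, 2 and 3. The CAsE-PE group held 3 arrays, after 30, 33.5 and 35 weeks of exposure, again named replicates 1, 2 and 3. The passage of the exposed cells was not given in the sources used here, and untreated cells of matched time in culture were not identified by the labels. Nothing in the labels says that passages or exposure times were separate cultures, so the p-values measure the spread between these arrays, in which technical and biological parts cannot be separated. Array medians lay between 91.7 and 97.2 intensity units. The correlation of log2 values over features with 1 gene symbol was 0.985 to 0.995 between arrays of a group and 0.957 to 0.970 between groups. With 3 arrays per group, the number of arrays limits the precision of each value. All differences are CAsE-PE minus RWPE-1 on the log2 scale, with n = 3 per group and the standard error (SE) of the limma fit.

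The comparison of both groups asks how gene expression differs between the immortal line and its arsenite-transformed descendant. The deepest falls were in ZNF667-AS1, an antisense RNA of a zinc finger gene, and SPARC, a secreted matrix protein. ZNF667-AS1 (feature 8031646, chromosome 19) went from a mean of 9.43 ± 0.32 (SD) to 4.69 ± 0.40, a log2 difference of −4.74 (SE 0.21) or 26.7-fold, with an adjusted p of 4.58e-06. SPARC (feature 8115327, chromosome 5) went from 10.79 ± 0.11 to 6.92 ± 0.18, a difference of −3.86 (SE 0.12, adjusted p = 2.00e-06). The next falls were in the zinc finger genes ZNF730 (−3.49), ZNF737 (−3.38) and ZNF560 (−3.24), the small nucleolar RNA SNORD114-3 (−3.46), the matrix proteoglycan VCAN (−3.35), the cell-surface gene FLRT2 (−3.34), the protease inhibitor TFPI2 (−3.19) and the annexin ANXA6 (−3.13). With chromosome Y and XIST left out, the largest rise was in CASP14, a caspase of cornifying epidermis. CASP14 went from 5.56 ± 0.44 to 9.68 ± 1.20 (difference 4.12, SE 0.50, adjusted p = 0.000674).

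The other large rises were in the axonemal dynein gene DNAH11 (2.93, SE 0.14), the cytochrome P450 gene CYP4X1 (2.86, SE 0.24), the epidermal lipid transporter ABCA12 (2.85, SE 0.18), the non-coding RNA LINC02893 (2.83, SE 0.20), TMTC1 (2.82, SE 0.23), PPP1R16B (2.61, SE 0.24), LINC00200 (2.44, SE 0.11), SUSD2 (2.44, SE 0.19) and SVEP1 (2.39, SE 0.24). Each of these genes had its 3 CAsE-PE arrays on one side of the 3 RWPE-1 arrays. In all, 1665 of 18417 genes were higher and 1604 lower in CAsE-PE, which is 17.8% of the genes tested. Among them 286 rose and 379 fell by at least 2-fold. The groups did not overlap for 3259 of the 3269 genes past the threshold and for 38.9% of all genes, where chance gives 10%. Without the passage 38 array 1888 genes passed, and without the array at 35 weeks 2094 passed.

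**Figure D1:**
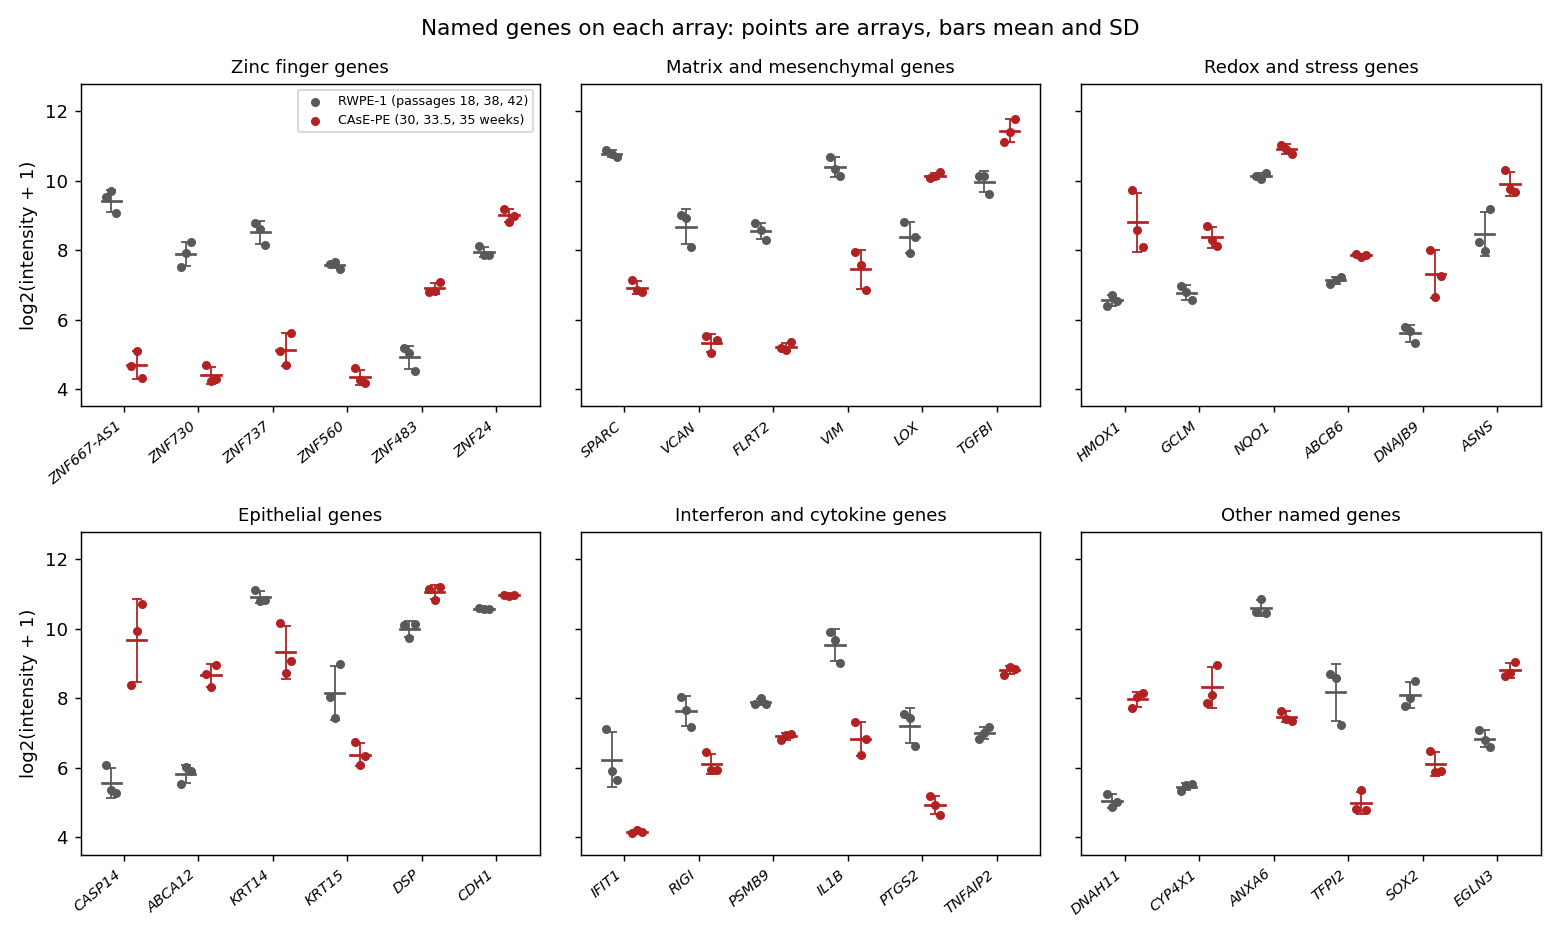
Log2 intensity of named genes on each array, on the vertical axis, with RWPE-1 arrays in grey and CAsE-PE arrays in red; horizontal bars give the mean and error bars the SD of 3 arrays. SPARC sits between 10.68 and 10.90 in RWPE-1 and between 6.79 and 7.13 in CAsE-PE, while CDH1 differs by 0.39.

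Zinc finger genes of the C2H2 class, which encode DNA-binding proteins often grouped in clusters on chromosome 19, changed in both directions. Of 524 measured, 79 fell, 48 rose and 397 did not pass the threshold. Adjusted over the list alone, 86 fell and 62 rose. Beside ZNF730, ZNF737 and ZNF560, the falls included ZNF90 (−2.75), ZNF583 (−2.54) and ZNF486 (−2.44), and 33 genes of the list fell by at least 2-fold. Only ZNF483 (1.99, SE 0.17) and ZNF24 (1.05, SE 0.13) rose by at least 2-fold, and ZNF24 lay among neighbouring genes with a median shift of 0.61, with which taken off it differed by 0.44. On chromosome 19, 49 of 244 zinc finger genes fell, 20.1%, against 77 of 1064 other genes, 7.24% (Fisher's exact test, two-sided p = 2.21e-08, chosen after the data were seen). On the other chromosomes 30 of 280 fell, 10.7%, and 41 rose.

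The zinc finger list as a whole had a mean difference of −0.09 and a median within 0.01 of 0, and camera placed it upward without passing the threshold (adjusted p = 0.751), so mean and test differ in sign. This list was chosen from what is known of this study and is not independent evidence of its direction. With the dimmest genes left out, 49 of its members fell, and rises numbered 27 without the passage 38 array and 31 without the array at 35 weeks. Family members share similar sequence, so single members of this family are uncertain.

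Genes of the mesenchymal list included more falls than rises. Of 30 measured, 12 fell, 3 rose and 15 did not pass the threshold, and the same numbers passed adjusted over the list alone. The intermediate filament gene VIM, vimentin, fell from 10.40 ± 0.28 to 7.45 ± 0.56 (−2.95, SE 0.25, adjusted p = 0.000114), and the growth factor gene TGFB2 (−2.84), the cadherin gene CDH11 (−2.46) and the surface antigen gene THY1 (−1.30) fell as well. VIM lay among neighbouring genes with a median shift of −0.64. LOX, a collagen cross-linking enzyme, rose by 1.77 (SE 0.20) and TGFBI, a matrix protein induced by TGF-beta, rose by 1.46 (SE 0.19). The gelatinase gene MMP9 differed by −0.27 (SE 0.14) and did not pass the threshold (adjusted p = 0.214). The camera test of the list gave an adjusted p of 0.000837, and an adjusted p = 0.545 with an estimated correlation.

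Among epithelial genes, the junction list held rises and no falls, and the basal list more falls than rises. Of 21 junction genes, 6 rose, 0 fell and 15 did not pass the threshold, with 8 higher adjusted over the list alone. They included the desmosomal genes DSP (1.06, SE 0.15) and DSG3 (1.03, SE 0.18), the claudin gene CLDN4 (0.58) and the E-cadherin gene CDH1 (0.39, SE 0.09, adjusted p = 0.0186). CDH1 and its list had limits: 2 junction genes rose without the passage 38 array (CDH1 adjusted p = 0.0811), and 3 without the passage 18 array or without the array at 35 weeks. With the median shift of their neighbours taken off (0.44 and 0.10), DSP differed by 0.62 and CDH1 by 0.28 (adjusted p = 0.0620). Of 14 basal epithelial markers, 7 fell and 1 rose, both over all genes and adjusted over the list alone. The keratin genes KRT15 (−1.77, SE 0.34) and KRT14 (−1.60, SE 0.31) and the laminin gene LAMB3 (−1.48) fell, whereas TRIM29 was higher by 0.48 (SE 0.14), a call lost without the passage 38 array (adjusted p = 0.159). Leaving out the passage 18, passage 38, 33.5-week or 35-week array left 4 basal genes lower. Camera gave an adjusted p of 0.000837 for junction genes and 0.0215 for basal genes, the latter 0.0647 without the 33.5-week array. For each of these lists the adjusted p = 0.545 with an estimated correlation.

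Luminal, squamous and stem cell genes moved both ways. Of 18 luminal prostate markers, 4 rose and 3 fell, with 4 lower adjusted over the list alone and again 4 higher. The prostate stem cell antigen gene PSCA (1.35, SE 0.15) and NDRG1 (0.81, SE 0.15) rose. The pioneer factor gene FOXA1 fell (−0.83, SE 0.12), as did STEAP2 (−0.95, SE 0.26), whose call was lost without the passage 42 array (adjusted p = 0.0983). Of 30 squamous differentiation genes, 3 rose and 4 fell, with 3 higher and 5 lower adjusted over the list alone: KRT13 fell (−1.39, SE 0.13) and SPRR1B fell (−0.63), while SPRR2A (0.98) and KRT10 (0.62) rose. The calls of SPRR1B (adjusted p = 0.102 without passage 38), SPRR2A (0.0598 without passage 42) and KRT10 (0.136 without 35 weeks) were lost with 1 array left out, and that of SPRR1B also with its neighbours' shift of −0.11 taken off (−0.52, adjusted p = 0.0515). Squamous counts ranged from 1 to 5 higher and 2 to 7 lower when arrays were left out in turn. Of 14 stem cell genes, 5 fell and 1 rose (7 and 3 adjusted over the list alone): the pluripotency factor gene SOX2 fell (4.01-fold, SE 0.21 on the log2 scale) with ALDH1A3 (−1.01, SE 0.11), and ALDH1A1 rose (1.38, SE 0.30). Between 3 and 6 stem cell genes fell with 1 array left out, and 3 rose without the passage 42 array. Camera gave adjusted p-values of 0.825, 0.951 and 0.291 for these 3 lists.

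Genes driven by NRF2, the transcription factor of the oxidative stress response, included rises, and no falls in the main fit. Of 28 measured, 10 rose, 0 fell and 18 did not pass the threshold, with 14 higher adjusted over the list alone, and their median difference was 0.45. Relative to the RWPE-1 mean, the list's median was 0.72 at 30 weeks, 0.27 at 33.5 and 0.32 at 35, and without the 30-week array 10 members rose and 2 fell. Haem oxygenase HMOX1 rose from 6.55 ± 0.15 to 8.81 ± 0.85 (2.25, SE 0.34, adjusted p = 0.00221), with 9.74 at 30 weeks, 8.59 at 33.5 and 8.09 at 35. The glutathione synthesis gene GCLM rose by 1.59 (SE 0.17), the cystine transporter SLC7A11 by 1.46, the aldo-keto reductase AKR1C1 by 1.46, the thioredoxin reductase TXNRD1 by 1.07 and the quinone reductase NQO1 by 0.76 (SE 0.11). AKR1C1 shares similar sequence with other AKR1C genes, so its value is uncertain. The camera test gave an adjusted p of 1.28e-05, and an adjusted p = 0.545 with an estimated correlation. HMOX1 is on chromosome 22, whose brighter genes had a median difference of 0.35.

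Genes of arsenic handling and stress proteins also included rises, and no falls in the main fit adjusted over all genes (0 lower in each list). After quantile normalisation 1 arsenic handling gene was lower. Of 13 arsenic handling genes, 4 rose (adjusted over the list alone, 4 higher and 1 lower): the transporters ABCB6 (0.72, SE 0.10) and ABCC1 (0.71, SE 0.13), the glutathione synthetase GSS (0.70) and the glucose transporter SLC2A1 (0.56). ABCC1 differed by 0.47 with its neighbours' shift of 0.24 taken off. Without the passage 42 or the 30-week array 1 arsenic handling gene fell. Of 13 metallothioneins, 2 rose over all genes and adjusted over the list alone, MT1X (0.54, SE 0.13) and MT1E (0.37, SE 0.11), and both calls were lost without the passage 38 array (adjusted p = 0.0817 and 0.126), that of MT1E with any 1 array left out and with its neighbours' shift of 0.07 taken off (0.30, adjusted p = 0.0845). MT2A differed by 0.07 (SE 0.10, adjusted p = 0.633). Metallothionein genes share similar sequence, so single members are uncertain. Of 18 heat shock and unfolded protein response genes, 6 rose, with 7 higher and 1 lower adjusted over the list alone. The co-chaperone DNAJB9 (1.71, SE 0.29), asparagine synthetase ASNS (1.44, SE 0.29), XBP1 (1.21) and ATF4 (1.00) were among them, and 10 members rose without the passage 42 array. DNAJB9 lay among neighbours with a median shift of 0.80, and with that shift taken off its difference was 0.91 (adjusted p = 0.0588). Camera gave adjusted p-values of 0.159 for arsenic handling, 0.0565 for metallothioneins and 0.0118 for stress proteins, the last 0.0917 after quantile normalisation and adjusted p = 0.545 with an estimated correlation. Without the passage 18 array the metallothionein list passed (adjusted p = 0.0205), as it did without the 35-week array (0.0303).

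Interferon response genes fell in CAsE-PE. Of 28 measured, 17 fell and 1 rose, over all genes and adjusted over the list alone, with a median difference of −0.83. The antiviral effector IFIT1 fell from 6.22 ± 0.79 to 4.16 ± 0.03 (−2.07, SE 0.32, adjusted p = 0.00233), the RNA sensor RIGI fell by 1.52 (SE 0.22), and IFI44 (−1.49), OAS2 (−1.44) and MX1 (−1.23) fell with them. EPSTI1 was higher by 0.46 (SE 0.11), a call lost without the passage 18 array (adjusted p = 0.0607). The median level of the 17 fallen genes was 7.48 at passage 18, 6.89 at passage 38 and 6.67 at passage 42, and 5.86, 5.71 and 5.71 at 30, 33.5 and 35 weeks. In the camera test the list had an adjusted p of 1.05e-06, and an adjusted p = 0.545 with an estimated correlation.

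Of 11 MHC genes, 1 fell and 0 rose, the antigen-processing immunoproteasome subunit PSMB9 (−0.99, SE 0.10), and 3 were lower adjusted over the list alone. All 11 differences were negative, with a median of −0.27, and camera gave an adjusted p of 0.0215, 0.0546 without the passage 38 array and adjusted p = 0.545 with an estimated correlation. Of 29 inflammatory genes, 5 fell and 2 rose, with 6 lower and 2 higher adjusted over the list alone. The cytokine gene IL1B (−2.70, SE 0.27) and the cyclooxygenase gene PTGS2 (−2.30, SE 0.23) fell with IL1A (−1.35), and TNFAIP2 rose (1.81, SE 0.12). LCN2 was higher by 0.77 (SE 0.19), a call lost without the passage 18 array (adjusted p = 0.0679), and by 0.46 (adjusted p = 0.118) with its neighbours' shift of 0.31 taken off. The camera adjusted p of this list was 0.110, and it passed without the passage 42 array (adjusted p = 0.0290) and without the 30-week array (0.0259, with 8 genes lower).

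Clustered protocadherin genes, cell-surface adhesion genes arranged in tandem on chromosome 5, fell. Of 29 measured, 17 fell and 0 rose, with 23 lower adjusted over the list alone, and the median difference was −0.78. PCDHB2 (−1.87, SE 0.24), PCDHB5 (−1.70, SE 0.46) and PCDHA12 (−1.56) were among them. With the shift of their window taken off (−0.74), in which protocadherins are members, PCDHB2 differed by −1.13 and PCDHB5 by −0.96 (adjusted p = 0.185). The call of PCDHB5 was lost without the passage 38 array (adjusted p = 0.116), when 9 members fell. The window of neighbouring genes that covers this cluster also differed within RWPE-1, with a median of −0.37 at passage 18 against 0.16 and 0.17 at passages 38 and 42. The list had a camera adjusted p of 2.68e-08, and an adjusted p = 0.598 with an estimated correlation. These genes share exons and similar sequence, so single members are uncertain.

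Of 27 HOX genes, regulators of body patterning, 2 rose and 3 fell, over all genes and adjusted over the list alone. HOXB9 (1.44, SE 0.25) and HOXB6 (0.66, SE 0.12, or 0.42 with its neighbours' shift of 0.25 taken off) on chromosome 17 rose, HOXD11 (−0.59, SE 0.11) fell and HOXD8 (−0.41, SE 0.12) fell, the last lost with any 1 array left out (highest adjusted p = 0.124, without the 33.5-week array). With 1 array left out, 2 HOX genes fell without the 33.5-week array and 1 in each of the other fits. With the shift of neighbouring genes taken off 9 fell, of which 2 were among the 3 (list adjusted p = 0.0508). Of 32 cancer/testis antigens, 1 fell, MAGEB6 (−0.39, SE 0.10), and 0 passed adjusted over the list alone. Its call was lost without the 35-week array (adjusted p = 0.102), and with its neighbours' shift of −0.28 taken off it differed by −0.11 (adjusted p = 0.486). Camera gave adjusted p-values of 0.240 for HOX genes and 0.198 for cancer/testis antigens.

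Genes of DNA and histone H3K9 methylation held 5 rises and 3 falls among 32, with 8 higher and 3 lower adjusted over the list alone. The H3K9 methyltransferase gene SETDB2 (0.58, SE 0.13) and the H3K27 methyltransferase gene EZH2 (0.45, SE 0.10) rose, and the H3K9 methyltransferase gene SUV39H2 (−0.69, SE 0.13) and MBD3 (−0.39, SE 0.11) fell. DNMT1, the maintenance DNA methyltransferase, differed by −0.07 (SE 0.13, adjusted p = 0.736). The calls of EZH2 (adjusted p = 0.0605 without passage 38) and MBD3 (0.113 without passage 18) were lost with 1 array left out, and 1 to 4 members rose in such fits, 1 without the passage 38 or the 35-week array. Without the passage 18, passage 38 or 35-week array 1 member fell. EZH2 lay among neighbours with a median shift of 0.60, and with that shift taken off its difference was −0.15 (adjusted p = 0.365). SUV39H2 differed by −0.38 (adjusted p = 0.0665) with its neighbours' shift of −0.31 taken off, and MBD3 by −0.26 (adjusted p = 0.142) with a shift of −0.13 taken off. For the list the camera test gave an adjusted p of 0.216.

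Replication-dependent histone genes held 5 rises and 2 falls among 57, over all genes and adjusted over the list alone. H2BC21 (1.41, SE 0.27) and the pseudogene H2BC19P (1.36, SE 0.28) rose, and H4C7 (−0.43, SE 0.09) and H4C16 (−0.54, SE 0.14) fell. H4C16 lay among neighbours with a median shift of −0.62, and its difference was 0.08 with that shift taken off. Between 0 and 7 histone genes fell with 1 array left out, 7 without the 33.5-week array, and 3 rose without the passage 38 or passage 42 array. The call of H4C7 was lost without the passage 38 array (adjusted p = 0.0654) and that of H4C16 without the 35-week array (0.109). Camera gave an adjusted p of 0.433 for histones, 0.0169 without the 35-week array, and the median (−0.03) and the mean (0.05) differ in sign. Of 64 cytosolic ribosomal protein genes, 7 rose and 1 fell, over all genes and adjusted over the list alone: RPL17 (1.06, SE 0.15) and RPL13 (0.56, SE 0.11) rose and RPS24 (−0.64, SE 0.12) fell. Between 2 and 4 ribosomal genes rose with 1 array left out. The camera adjusted p of ribosomal genes was 0.0967, with 0.0318 without passage 18 and 0.0469 without 35 weeks. Members of both families are near-identical to other copies, and their values are uncertain.

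Of 19 cholesterol synthesis genes, 4 rose, 0 fell and 15 did not pass the threshold, with 7 higher adjusted over the list alone: INSIG1 (1.44, SE 0.24) and SREBF2 (0.71, SE 0.10), regulators of sterol synthesis, with MSMO1 (0.55) and IDI1 (0.48). Without the passage 18 array 2 rose. INSIG1 lay among neighbours with a median shift of 0.65, and its difference was 0.79 (adjusted p = 0.0463) with that shift taken off. SREBF2 lay among neighbours with a median shift of 0.43, and its difference was 0.28 (adjusted p = 0.0962) with that shift taken off. Camera gave an adjusted p of 0.00393, and an adjusted p = 0.598 with an estimated correlation. Of 24 hypoxia and glycolysis genes, 5 rose and 2 fell, with 6 higher and 2 lower adjusted over the list alone. The oxygen sensor EGLN3 rose by 1.97 (SE 0.15) and VEGFA by 1.23 (SE 0.28), and the glucose transporter SLC2A3 (−1.51, SE 0.10) and the lactate dehydrogenase LDHB (−0.63, SE 0.13) fell. SLC2A3 and LDHB lay in a chromosome 12 run with a median shift of −0.60, and with their window's shift taken off they differed by −0.92 and −0.01. VEGFA was lost without the passage 38 array (adjusted p = 0.0663), when 1 member rose, and 3 members rose without the 35-week array. Camera gave an adjusted p of 0.0202 for this list, 0.106 without the passage 42 array, 0.127 after quantile normalisation, 0.132 with the dimmest genes left out and adjusted p = 0.675 with an estimated correlation.

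Of 32 proliferation genes, 3 rose and 3 fell, over all genes and adjusted over the list alone. The mitotic transcription factor gene FOXM1 (1.00, SE 0.14) and the replication helicase gene MCM5 (0.66, SE 0.13) rose, and the mitotic genes CENPF (−0.60, SE 0.14) and CDC20 (−0.59, SE 0.15) fell. FOXM1 and CENPF lay among neighbours with median shifts of 0.64 and −0.59, and with these taken off they differed by 0.36 (adjusted p = 0.105) and −0.01 (0.997). MCM5 differed by 0.42 (adjusted p = 0.0498) with its neighbours' shift of 0.24 taken off. Of 20 p53 targets, 1 rose, TIGAR (0.59, SE 0.16), and 0 passed adjusted over the list alone. TIGAR differed by 0.50 (adjusted p = 0.0577) with its neighbours' shift of 0.08 taken off. The calls of CENPF (adjusted p = 0.0839), CDC20 (0.102) and TIGAR (0.0900) were lost without the passage 38 array, and 0 to 2 proliferation genes fell with 1 array left out. Of 27 genes of the RAS and MAPK pathway and its feedback, 5 fell and 1 rose, over all genes and adjusted over the list alone: PHLDA1 (−0.91, SE 0.11), TGFA (−0.76, SE 0.19) and the cyclin gene CCND1 (−0.65) fell and ETV5 rose (0.61, SE 0.10). TGFA was lost without the 35-week array (adjusted p = 0.0992), and 1 member fell without passage 18, passage 38, 33.5 weeks or 35 weeks. Camera gave adjusted p-values of 0.216, 0.547 and 0.547 for these 3 lists.

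Markers of other cell types changed in few members. Of 13 fibroblast markers, FBLN1 rose (1.27, SE 0.13), and POSTN (−0.52, SE 0.13) and PDGFRB (−0.32, SE 0.09) fell, the same 1 and 2 adjusted over the list alone. POSTN was lost without the passage 18 array (adjusted p = 0.0919) and PDGFRB with any 1 array left out (highest 0.156, without passage 38). With their neighbours' shifts of 0.45 and −0.18 taken off, FBLN1 differed by 0.82 and PDGFRB by −0.13 (adjusted p = 0.386). The list's median was −0.11 and its mean 0.03, with camera downward (adjusted p = 0.951). Of 12 leukocyte markers, 0 rose and 2 fell, also adjusted over the list alone: CD68 (−0.89, SE 0.16) and CD14 (−0.43, SE 0.11), the latter lost without the 35-week array (adjusted p = 0.0989). The camera adjusted p of leukocyte markers was 0.0602, and 0.0259 without the 30-week array. Of 9 endothelial markers, 0 passed in limma, 0 adjusted over the list alone, and the camera adjusted p was 0.795. Of 9 neuroendocrine markers, ENO2 rose (0.47, SE 0.10), a call lost without the passage 38 array (adjusted p = 0.0687), with 1 higher and 3 lower adjusted over the list alone and a camera adjusted p of 0.547. Of all 29 lists, 10 passed with the preset correlation, 5 upward and 5 downward, and 0 with an estimated correlation.

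**Figure D2:**
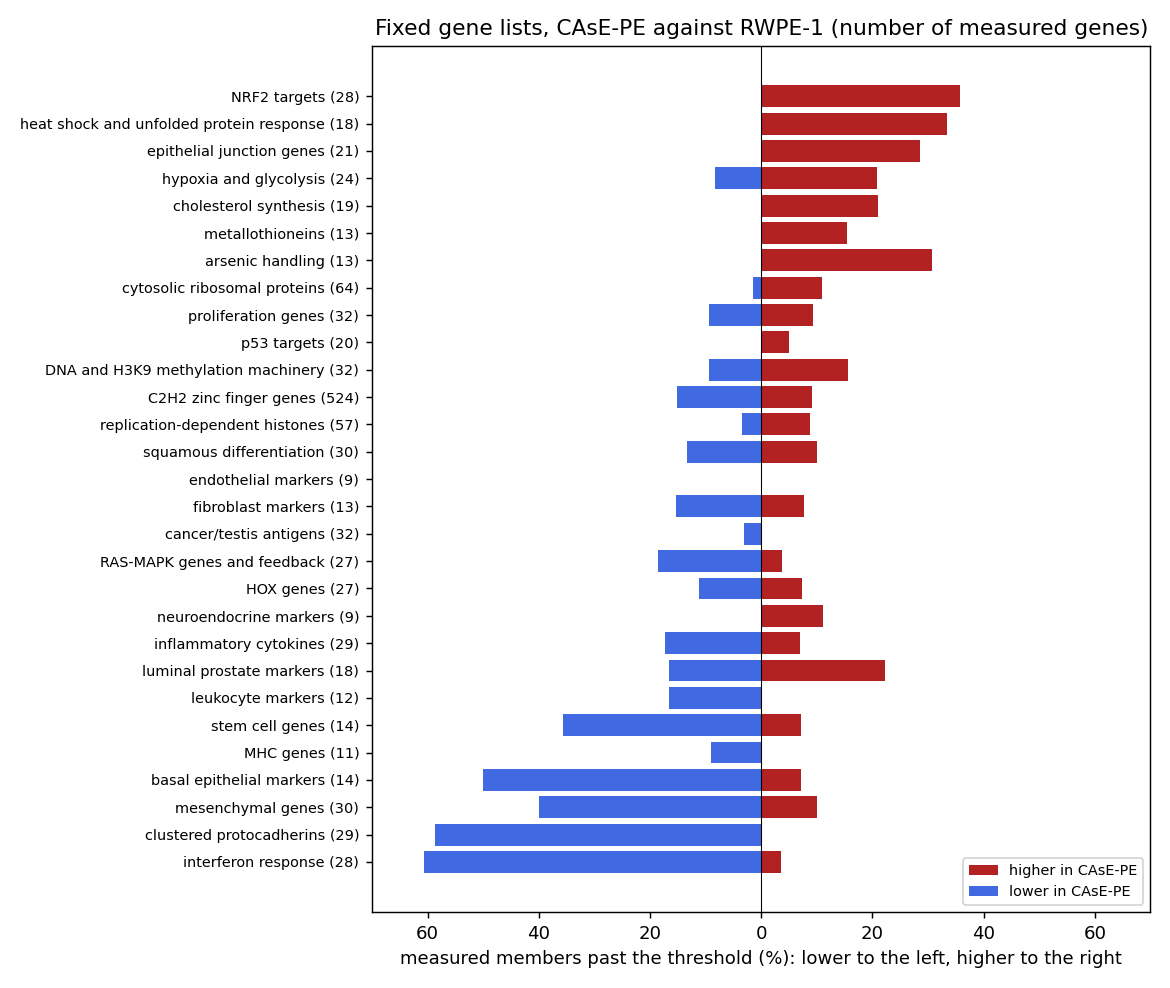
Share of measured members past the threshold in each fixed gene list, in percent on the horizontal axis, with genes lower in CAsE-PE drawn to the left in blue and higher ones to the right in red; lists are ordered by median difference and the number of measured genes stands in brackets. The interferon list has 17 of 28 members lower and the NRF2 list 10 of 28 higher.

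The trends within each group ask how far the untreated line moved between passages and the transformed line between 30 and 35 weeks. With passage, 4 genes fell and 0 rose past the threshold in limma, where 1072 genes had an unadjusted p under 0.05. From passage 18 to passage 42, the antisense RNA LIMD1-AS1 fell by 1.99 (SE 0.22), the N-cadherin gene CDH2 fell by 1.63 (SE 0.19) and IFIT1 fell by 1.48 (SE 0.17), each with an adjusted p of 0.0381. The remaining gene was on chromosome Y, which the rule for named genes leaves out. IFIT1 measured 7.13, 5.91 and 5.64 at passages 18, 38 and 42. After quantile normalisation, or with weeks left out of the model, 0 genes passed the passage test.

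With weeks of exposure, 28 genes rose and 18 fell, and 2072 had an unadjusted p under 0.05. CASP14 rose by 2.33 (SE 0.18) over the 5 weeks, from 8.38 at 30 weeks to 9.94 and 10.73 at 33.5 and 35. The relaxin receptor RXFP1 rose by 2.39 (SE 0.22) from 4.22 to 6.21 and 6.51, and PYGO1 by 2.16 (SE 0.28). ZNF750, a regulator of epidermal differentiation, fell by 2.55 (SE 0.41) from 8.99 to 6.40 and 6.69, DMGDH fell by 2.02 (SE 0.25) and the cyclin gene CCNA1 fell by 1.99 (SE 0.29). HMOX1 fell by 1.65 (SE 0.19). With 3 time points, a trend cannot be separated from a step after the 30-week array, which differs most from the others of its group. Each trend rests on 3 arrays with 2 residual degrees of freedom in the model, and 3 genes passed after quantile normalisation.

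The design also asked whether the changed genes were spread evenly over chromosomes. On chromosome 22, 146 of 423 genes were higher in CAsE-PE, 34.5% against 8.44% elsewhere (Fisher's exact test, two-sided, adjusted p = 1.71e-47), and 6 were lower. Of its 317 brighter genes 74.8% had a positive difference, with a median of 0.35. The share of higher genes was also above that elsewhere on chromosome 15 (19.8%), 9 (17.8%), 18 (16.3%), 7 (16.2%), 17 (15.3%), 16 (13.2%) and 5 (11.6%), and the share of lower genes on chromosome 10 (18.3%), 20 (15.7%), 13 (13.6%) and 1 (11.5%), and on chromosome 12 with 118 of 982 genes. On chromosome 19, 2.29% of 1308 genes were higher. Of 23 genes on chromosome Y 11 were higher and 0 lower (adjusted p = 4.12e-06), and its 10 brighter genes had a median difference of 3.42, the largest of any chromosome. In all, 14 of the tests found an excess. These tests count genes as independent, whereas neighbouring genes moved together and all came from the same 6 arrays. Their p-values therefore describe counts of genes and not replicated cultures.

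Neighbouring genes moved together. The mean product of the differences of adjacent genes was 0.0414, above the highest of 1000 shuffles of gene order within chromosomes at 0.0118 (permutation p = 0.000999, the smallest they can give). Gene order was taken from the RefSeq annotation of GRCh38.p14. Of 493 windows of 25 brighter neighbouring genes, 25 were shifted up and 13 down past a limit of 0.35. The longest run, of 5 windows on chromosome 7 from ALKBH4 to ZNF777, had a median difference of 0.61, with 81 of 120 genes higher and 3 lower. On chromosome 17 a run of 4 windows from SPATA20 to SSTR2 had a median of 0.45, and on chromosome 22 a run of 3 windows from NOL12 to CYP2D6 had 0.43. On chromosome 20 a run of 4 windows from C20orf96 to NAPB had a median of −0.51, with 60 of 100 genes lower and 0 higher. Shorter runs of 2 windows were lower on chromosome 12 from SLC2A3 to MED21 (−0.60), on chromosome 10 from RPP38-DT to ZNF33B (−0.56) on chromosome 1 from C1orf74 to LBR (−0.62) and on chromosome 13 from STK24 to CHAMP1 (−0.41). Others were higher on chromosome 6 from DUSP22 to TPMT (0.45) and on chromosome 15 from PPIP5K1 to NEDD4 (0.44), and 10 runs were of 1 window. The chromosome 7 run stood at 0.55, 0.62 and 0.59 in the CAsE-PE arrays and between −0.07 and 0.04 in the RWPE-1 arrays, relative to the RWPE-1 mean. The windows were chosen after the data were seen.

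**Figure D3:**
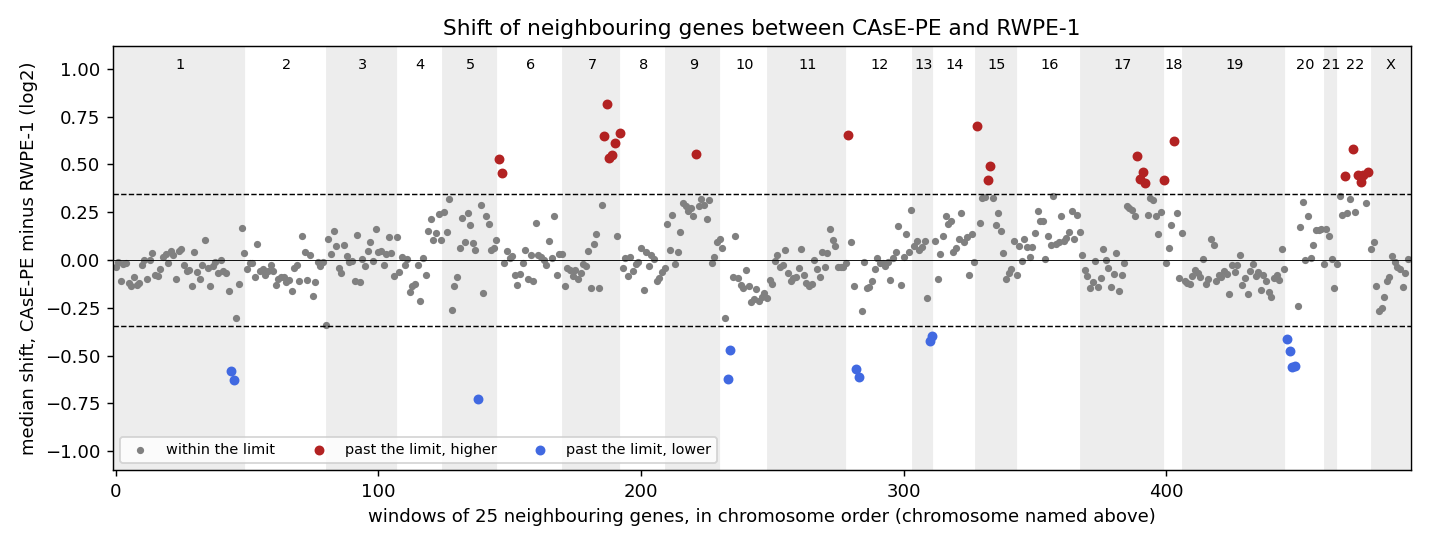
Median log2 shift between CAsE-PE and RWPE-1 in windows of 25 neighbouring genes, on the vertical axis, in chromosome order on the horizontal axis; each point is a window, dashed lines mark the limit of 0.35, and red and blue points are windows past it. Of 493 windows, 25 lie above and 13 below the limits, with the longest run on chromosome 7.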

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

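Features outside the named comparisons also differed between the groups. Of the 1754 features that name several genes, 201 passed the threshold, 121 higher and 80 lower in CAsE-PE. Of the 12038 features that the annotation does not list, 941 passed, 705 higher and 236 lower, and their median log2 level was 5.45. These features were left out of all gene counts, and no explanation was tested for them.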

How the results depend on the processing

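Alternatives with window medians, other pseudocounts, other window sizes and the zinc finger counts were chosen after seeing the data. No paired analysis was possible because the labels give the arrays passages and exposure times and no shared replicate numbers. Of 107 named genes, all kept their direction and side of the threshold with no pseudocount or with the mean of all features, 101 did after quantile normalisation, 58 without moderation of the variance and 47 in the test against a 1.5-fold change. Of 97 called genes, 71 stayed past the threshold with each array left out in turn and 26 lost it at least once, with the same sign throughout.

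Without moderation 1285 genes passed, 580 higher and 705 lower, with 37 zinc finger genes lower. With array weights 5342 passed, 2596 higher and 2746 lower. Against a 1.5-fold change 356 passed, 126 higher and 230 lower, with 30 zinc finger genes lower, and with the dimmest genes left out 49 zinc finger genes were lower, since fewer genes enter or a larger change is asked. Of the calls in the main comparison, 2828 were shared with quantile normalisation, 3132 with median centring and 2081 with window medians taken off. With 1 array left out the total ranged from 1888 to 3151, higher genes from 949 to 1665 and lower genes from 939 to 1519, with fewer samples in each fit. The lists past the threshold were 10, against 0 with an estimated correlation, 6 with fry for 1 direction and 26 with fry for either direction. In 1 direction fry lost protocadherins and NRF2 targets (adjusted p = 0.0636 each), cholesterol synthesis (0.132) and hypoxia and glycolysis (0.307). The passage trend went from 4 genes to 0 after quantile normalisation and to 0 with weeks left out, and the week trend from 46 to 3 after quantile normalisation. Camera asks whether a list changes more than other genes, and fry whether its members change at all, so their counts answer different questions. Beyond that, the cause was not tested for array weights, fry and the trends.

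With window medians taken off, EZH2 went to −0.15 and H4C16 to 0.0821, and the protocadherin list had an adjusted p of 0.54 in the other direction. The protocadherins make up much of their own window, so this follows from the construction. Windows past the limit numbered 38, with 39 for 15 genes, 38 for 50 genes, 37 with dim genes kept and 37 to 51 with 1 array left out. Intensities came without background values, so how far dim genes lie above background stays unknown.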

Other observations

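Tests chosen only after their result was seen are those of other splits for genes and lists, of passage drift, of run length, of single RWPE-1 arrays, of the zinc finger counts, of the small nucleolar RNAs and of the genes rising with weeks. Non-coding RNAs of an imprinted cluster on chromosome 14 were lower in CAsE-PE, a group chosen after its values were seen. All 6 measured SNORD113 and SNORD114 small nucleolar RNAs fell, with a median difference of −1.96. Of other genes 8.68% were lower (Fisher's exact test, two-sided p = 4.33e-07, on a group picked because of SNORD114-3). The median level of the 6 was 5.27 to 5.52 on the RWPE-1 arrays and 3.36 to 3.47 on the CAsE-PE arrays. All of these lay below the array medians of 6.53 to 6.62, so how far they lie above background is unknown. Family members share similar sequence, so single members are uncertain, and whether the 6 changed separately was not tested. SNORD114-3 fell by 3.46 and SNORD113-4 by 2.76 (adjusted p = 4.58e-06 and 4.58e-06), and MEG3, the long non-coding RNA of the same cluster, fell by 1.85 (adjusted p = 6.22e-05). Among protein-coding genes of the cluster, DLK1 (−0.07, adjusted p = 0.712) and RTL1 (−0.11, adjusted p = 0.481) did not pass the threshold. Without detection calls, it is not known whether they were expressed, so a contrast with the non-coding RNAs stays open. The sodium channel subunit genes SCNN1B (2.11) and SCNN1G (1.75) rose, with the protease inhibitor gene SLPI (1.73) and the epidermal transcription factor gene GRHL1 (1.94). The matrix genes FBN2 (−2.85), MFAP2 (−2.55) and LAMA1 (−2.53) fell. These genes were picked as examples outside the rule for named genes, and other matrix genes such as TGFBI (1.46) rose.

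The array at 30 weeks stood apart from the later arrays over all genes. Its correlation with the arrays at 33.5 and 35 weeks was 0.985 and 0.986, and theirs with each other 0.994. Within RWPE-1, passage 42 correlated at 0.985 and 0.988 with passages 18 and 38, and those with each other at 0.995. Relative to the RWPE-1 mean, the median of brighter genes on chromosome 13 was 0.12 at 30 weeks and −0.14 and −0.12 at 33.5 and 35 weeks. On chromosome 14 it was 0.22 against 0.01 and 0.01, and on chromosome X −0.19 against −0.02 and −0.06. Among the 28 genes rising with weeks, 4 were on chromosome X (MAP7D2, POLA1, APOO and MID1; Fisher's exact test, two-sided p = 0.0201) and 5 were C2H2 zinc finger genes (ZNF90, ZNF280B, ZNF429, ZNF486 and ZNF493; p = 0.00105). ZNF486 was at 5.55, 6.85 and 7.11 at 30, 33.5 and 35 weeks and at a mean of 8.95 ± 0.08 (SD, n = 3) in RWPE-1.

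The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3269 genes and the highest other 0, so 1 split gave as many. For lists with the preset correlation, 2 of 10 splits gave as many as the real 10, and the highest other gave 11. For windows of neighbouring genes, 1 split gave as many as the real 38, and the highest other gave 32. Every other split sets 2 arrays of a group against 1, so part of the difference between groups stays in it. The difference also widens the spread within each side of such a split, which lowers the number of genes that pass. The 0 genes of the other splits are therefore no evidence for the real split.

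The shifts of neighbouring genes were set against technical and culture explanations. A bias that depends on intensity would leave little of the shift once a smooth trend on intensity was taken off, and a median share of 0.961 of it stayed (95% bootstrap interval 0.941 to 0.993). Drift that CAsE-PE shared with the untreated line would give a positive correlation across the windows past the limit. CAsE-PE minus passage 38 and passage 42 minus passage 18 correlated there at −0.518 (interval −0.699 to −0.247, over windows, which are not independent replicates). Between these passages, this argues against shared drift in the same direction. The correlation does not measure the size of the passage changes. Relative to the RWPE-1 mean, the chromosome 7 run stood at 0.03, 0.04 and −0.07 at passages 18, 38 and 42, beside a shift of 0.61. A chromosome 15 window from NIPA1 to FAN1 stood at 0.18, −0.05 and −0.09, beside 0.69. A negative correlation could also come from RWPE-1 moving away from a state that CAsE-PE kept, so drift of the untreated line alone stays open. Gain or loss of chromosome segments needs shifts over many genes, and 4 runs spanned 3 or more windows, but these runs had been seen when the test was chosen, so their number does not decide. DNA was not analysed here, and gain or loss of DNA, whether with arsenite or with time in culture, stays open beside shared regulation of neighbouring genes. Chromosome Y, with the largest median difference of any chromosome, was in none of these windows, so these tests do not bear on it.

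The fall of zinc finger genes was set against loss of DNA around them. Their nearest neighbours that are not zinc finger genes, 78 genes, had a median difference of −0.102 (interval over genes −0.169 to −0.0406). The 79 fallen genes, picked for falling, had −0.814. For the group, this argues against losses of DNA that reach these neighbours. The neighbours lie beyond any adjoining zinc finger genes and were not filtered for brightness, so loss within a cluster or of single genes stays open. From passage 18 to passage 42 the fallen genes changed by a median of 0.0235 (interval over genes −0.0335 to 0.113). From passage 38 to CAsE-PE they changed by −0.938. As a group they thus showed no fall between these passages. Calls favour genes with little spread among the RWPE-1 arrays, so this does not decide on drift, and drift of the exposed line was not tested. A change in the control of these genes in the transformed line may be involved, as a hypothesis, and DNA methylation was not analysed here.

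The fall of interferon response genes was set against drift with passage and against a single array. The 17 fallen genes changed by a median of −0.872 from passage 18 to passage 42 (interval −1.15 to −0.389), all 17 downward, and by −1.22 from passage 38 to CAsE-PE, with −0.787 from passage 42. Drift with passage and an effect of arsenite transformation cannot be told apart, since the passage of the exposed cells is not given in the sources used here. The interval lies past the fall of 0.305 under which drift was to be argued against. Only part of it lies past the fall of 0.609 set for drift as the cause. It comes from resampled genes, which can move together, and holds no spread between arrays or cultures, so it does not decide. A single deviating RWPE-1 array is argued against by 14 of the genes staying lower in the smallest count with 1 such array left out.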
